A study of Mus musculus with 2 samples.

How the data were processed

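Circular chromosome conformation capture with sequencing (4C-seq) was run on primary mouse bone marrow-derived macrophages (BMDMs) of a C57BL/6 background, cells grown from bone marrow in medium conditioned by L929 cells and taken on day 7 of differentiation. In 4C-seq, chromatin is cross-linked, cut and ligated, and inverse PCR from a chosen viewpoint recovers the DNA that was ligated to it, so that the reads at a place in the genome count its ligation to the viewpoint. There was 1 library with a viewpoint at the transcription start site of Ccl2 and 1 library with a viewpoint at that of Jun, both from untreated cells. Per the labels' protocols, cross-linking used 2% formaldehyde for 10 min, the first digestion used the 4 bp cutter DpnII and the second the 4 bp cutter written as Csp61 in the labels, and 8 PCRs from 200 ng of 4C template were pooled before single-read Illumina sequencing. The protocol mentions no molecular identifiers, so PCR copies of 1 ligation product count as separate reads.

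The genome build is mm9, per the submitters' processing notes; the aligner and its version are not given in the sources used here. Each deposited file covers the viewpoint chromosome (chromosome 11 for Ccl2, chromosome 4 for Jun) in bins of 16 bp, with values only in the bin that holds the centre of a DpnII fragment. The file headers name a value for the 3′ and the 5′ end of each fragment, a multiplicity for each end, the fragment length and lengths to the second cutter, and these names stand 1 column to the right of their values because of an empty header cell. The deposited end values are estimated counts of reads, not scaled to depth: low values pile up just under whole numbers (of the values from 0.05 to 10 on unique ends, 70.3% in the Ccl2 file and 72.8% in the Jun file lie within 0.1 of a whole number). This reading of the unit rests on the values, and the way in which single reads were weighted is not given in the sources used here. The multiplicity, read as the number of places in the genome that share the sequence of an end, ran from 1 upwards. The lengths of neighbouring fragments, averaged, equalled the distance between their positions within 16 bp in 99.997% of cases in both files, which shows that positions are fragment centres.

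The estimated counts were rounded to whole reads. Only ends with 1 copy in the genome were used, 424612 of 486170 ends with a value for Ccl2 and 496746 of 596304 for Jun. The annotation given with the data is of GRCm38.p6 and not mm9, so the viewpoint position was taken as the centre of the fragment whose end had the most reads, as laid down in advance for this case: position 81848193 on chromosome 11 for Ccl2 and position 94721073 on chromosome 4 for Jun. Ends closer than 5 kb to it were left out as undigested or self-ligated product. Distances are in kb from that position, and "lower" and "higher" sides refer to mm9 coordinates.

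With 1 library per viewpoint no test between samples could be made, and no p-value is given. Intervals are exact binomial (Clopper-Pearson) 95% intervals for shares, intervals from 1000 bootstrap draws of 20 kb blocks for decay exponents and side shares, from 200 such draws for the position of a drop in coverage, and from 1000 redraws of the fragment ends inside a region for its fold. They cover counting error or scatter along the chromosome within 1 library, not differences between cultures, and reads without molecular identifiers are not independent molecules.

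4 results were fixed before the data were examined: the percentage of reads within 100 kb of the viewpoint; the decay exponent, which is the slope of log10 reads per kb on log10 distance over 10 bins of equal log width from 20 kb to 2000 kb; the percentage of reads between 20 and 500 kb that lie on the lower side; and contact regions. A contact region is a run of 10 kb windows, moved by 5 kb from 20 to 1000 kb on either side, with at least 3 times the reads expected from the decay line of both sides pooled and at least 5 ends with a read. By the rule fixed with them, up to 10 contact regions with the highest ratio of observed to expected reads and the 3 longest gaps (runs of windows at 1/3 of the expectation or less) are named per viewpoint. The position of the drop in coverage, at which a step of 5 kb best parts each side from 20 to 2000 kb into an inner and an outer share of ends with a read (binomial maximum likelihood), was added after seeing the data. Gene lists had been fixed too: the chemokine cluster around Ccl2 (6 genes), the second chemokine cluster of the chromosome (5 genes), other genes flanking Ccl2 (12), Schlafen genes (7), genes flanking Jun (12) and Cyp2j genes (8). Every symbol was found on its chromosome in the GRCm38.p6 gene table, but no member could be given a signal, because that table's positions do not apply to mm9; it was used for gene names and gene order only.

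The code was tested on simulated reads at the real ends of each library, 20 draws each with an exponent of -1.3. It recovered -1.34 ± 0.02 (SD) at the Ccl2 positions and -1.32 ± 0.03 at the Jun positions. In 10 of these draws with added 20 kb contact regions it found 20 of 20 regions of 4-fold and 20 of 20 of 8-fold at the positions of each library, and 0 false regions, and a drop in coverage placed at 400.0 kb was found there in every draw. The draws with regions had equal sides, and the simulated drop was a sharp step. Simulated reads also covered far ends more densely than those of Ccl2 or of the lower side of Jun. These rates therefore test the code and need not hold for the real libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used. Alternatives covered a ceiling on strongly amplified ends, presence of a read instead of reads, a minimum of 2 reads, the zone left out, the distance ranges, the window, the threshold, the expectation, ends with several copies and fragments without a second-cutter site.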

Results

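The 3D contacts of 2 promoters were profiled in untreated BMDMs. Ccl2 encodes a CC chemokine that attracts monocytes, and Jun encodes a subunit of the AP-1 transcription factor. The series concerns transcription from cis-regulatory elements, and the 4C-seq profiles show how often chromatin along the chromosome was ligated to each promoter. The Ccl2 library held 1248937 reads on unique fragment ends of chromosome 11, and the Jun library held 1652054 on chromosome 4. The single end next to the viewpoint took 20.7% of them for Ccl2 (258628 reads) and 28.0% for Jun (462999 reads), and the zone of 5 kb on either side took 27.8% and 33.5%. Outside that zone 901507 reads on 8145 ends remained for Ccl2 and 1098887 reads on 9507 ends for Jun. There was 1 library per viewpoint, so every value below describes that library.

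The first question was how far the contacts of each promoter reached. The Ccl2 promoter had a compact contact zone. From 20 to 100 kb, 76.3% of ends on the lower side (95% interval 71.4 to 80.8%, 338 ends) and 83.6% on the higher side (79.1 to 87.5%, 323 ends) had a read. From 100 to 500 kb the shares were 14.2% (12.6 to 15.9%) and 24.2% (22.1 to 26.3%). Coverage dropped at 105 kb on the lower side (block bootstrap interval 60 to 450 kb) and at 165 kb on the higher side (140 to 205 kb), which are positions 81743193 and 82013193 of chromosome 11 in mm9. Inside these positions 75.8% and 82.1% of ends had a read, and outside them, up to 2000 kb, 6.50% and 10.9%. The lower position was poorly fixed, as its interval shows, and the fit of a step returns a position for a gradual fall too. In 20 kb windows from 40 to 140 kb the lower-side shares were 88.7%, 56.1%, 57.5%, 38.6% and 20.9%, a fall over several windows. The higher-side shares from 140 to 280 kb were 85.9%, 48.5%, 31.1%, 26.1%, 13.4%, 23.3% and 7.95%, so that fall was not a sharp step either. In GRCm38.p6 gene order, the protein-coding genes that follow Ccl2 on the higher side are the CC chemokine genes Ccl7, Ccl11, Ccl12, Ccl8 and Ccl1 and then Tmem132e, while 1700071K01Rik and Asic2, an acid-sensing ion channel gene, are next on the lower side. Which of these genes lie inside the zone was not analysed here for want of an mm9 annotation.

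The Jun promoter had a contact zone of very different extent on its 2 sides. On the lower side coverage dropped at 135 kb, at position 94586073 of chromosome 4 (block bootstrap interval 80 to 565 kb). There too the fall was gradual, with 63.9%, 35.8%, 44.1% and 21.4% of ends in the 20 kb windows from 80 to 160 kb. On the higher side it stayed high much farther out, and the drop was placed at 895 kb, at position 95616073 (860 to 970 kb). Between 20 and 895 kb, 88.8% of 3340 ends on the higher side had a read (95% interval 87.7 to 89.9%) against 16.4% of 3045 ends on the lower side (15.1 to 17.8%). The higher side held 730913 reads in that range and the lower side 52803, a ratio of 13.8. Beyond the drop on the higher side, up to 2000 kb, 5.35% of ends had a read (4.61 to 6.17%). These reads lay unevenly, and this fall was not a sharp step either. In 20 kb windows the share was 30.3% from 900 to 920 kb, 38.2% from 960 to 980 kb and 24.4% from 980 to 1000 kb. It was 12.1% from 1000 to 1020 kb and 1.19% from 1080 to 1100 kb. The next protein-coding genes on the higher side in GRCm38.p6 gene order are Fggy, a carbohydrate kinase gene, Hook1, which encodes a microtubule-linked adaptor, and then 7 Cyp2j genes, of a family of arachidonate epoxygenases. Those on the lower side are Mysm1, a histone H2A deubiquitinase gene, Eqtn and Tek, an angiopoietin receptor gene. How many of them lie within the covered stretch was not analysed here.

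**Figure D1:**
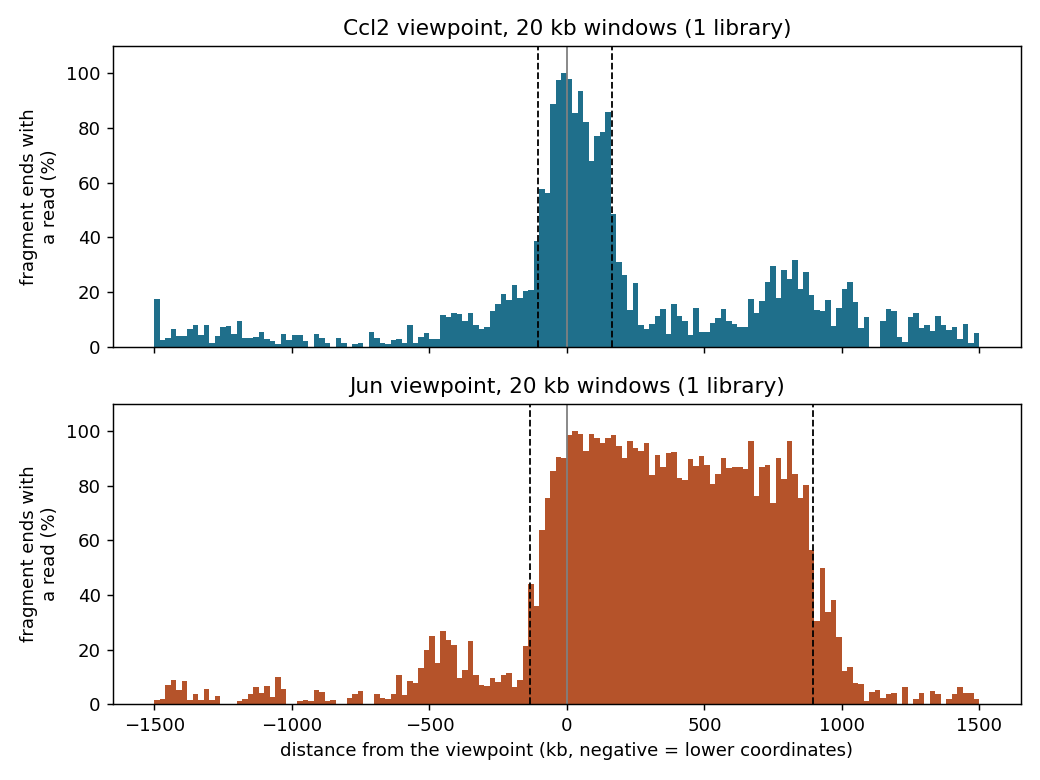
Percentage of unique fragment ends with at least 1 read (vertical axis) in 20 kb windows against the distance from the viewpoint in kb (horizontal axis, negative for lower coordinates), 1 library each; the grey line is the viewpoint and dashed lines are the drops in coverage. The drops lie at 105 and 165 kb for Ccl2 and at 135 and 895 kb for Jun, where the higher side is covered at 88.8% up to the drop. The fall was gradual on both sides of each viewpoint.

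The second question was how the signal was shared out along the chromosome. Of the reads used, 38.6% lay within 100 kb of the Ccl2 viewpoint (348151 of 901507 reads, exact interval 38.5 to 38.7%) and 22.5% within 100 kb of the Jun viewpoint (247311 of 1098887, 22.4 to 22.6%). Within 1000 kb the order was the other way round, with 50.9% for Ccl2 and 78.3% for Jun. The class from 100 to 500 kb held 9.31% of the reads of Ccl2 and 34.3% of those of Jun, and that from 500 to 1000 kb held 2.98% and 21.5%. Beyond 10 Mb lay 36.5% of the Ccl2 reads, on 1.38% of the ends there (1.34 to 1.42%), and 17.0% of the Jun reads, on 1.09% (1.06 to 1.12%). Within 100 kb, the class from 5 to 20 kb held 163853 reads of Ccl2 (18.2%) and 71821 reads of Jun (6.54%), and that from 20 to 100 kb held 184298 and 175490 reads. On both sides together, 98.7% of Ccl2 ends (95.3 to 99.8%) and 94.5% of Jun ends (89.0 to 97.8%) had a read from 5 to 20 kb, and 79.9% (76.6 to 82.9%) and 88.7% (85.9 to 91.2%) from 20 to 100 kb. Counted by ends with a read and not by reads, 8.32% of the Ccl2 signal and 6.72% of the Jun signal lay within 100 kb.

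The decay of reads with distance from 20 to 2000 kb had an exponent of -1.35 for Ccl2 (block bootstrap interval -1.44 to -1.20) and -1.12 for Jun (-1.45 to -0.96). The difference, Jun minus Ccl2, was 0.23 with an interval from -0.16 to 0.41 that includes 0. Blocks were redrawn whatever their distance, and the nearest bin lies within the nearest 20 kb block of each side. Draws without these blocks lacked that bin, which enters the width of the exponent intervals. The libraries were thus not distinguished by this measure, which does not show that their decay was alike. Up to 500 kb only, the exponents were -1.68 and -0.57 and their difference 1.11. Counted by ends with a read, they were -0.83 and -0.66 from 20 to 2000 kb, outside the intervals above. The Jun profile did not follow a straight line: on its higher side reads per kb were 543 in the bin centred on 399 kb, 582 in that on 632 kb and 2.64 in that on 1589 kb. For Ccl2, the exponent was -1.53 on the lower side (-1.62 to -1.11) and -1.20 on the higher side (-1.28 to -1.11).

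**Figure D2:**
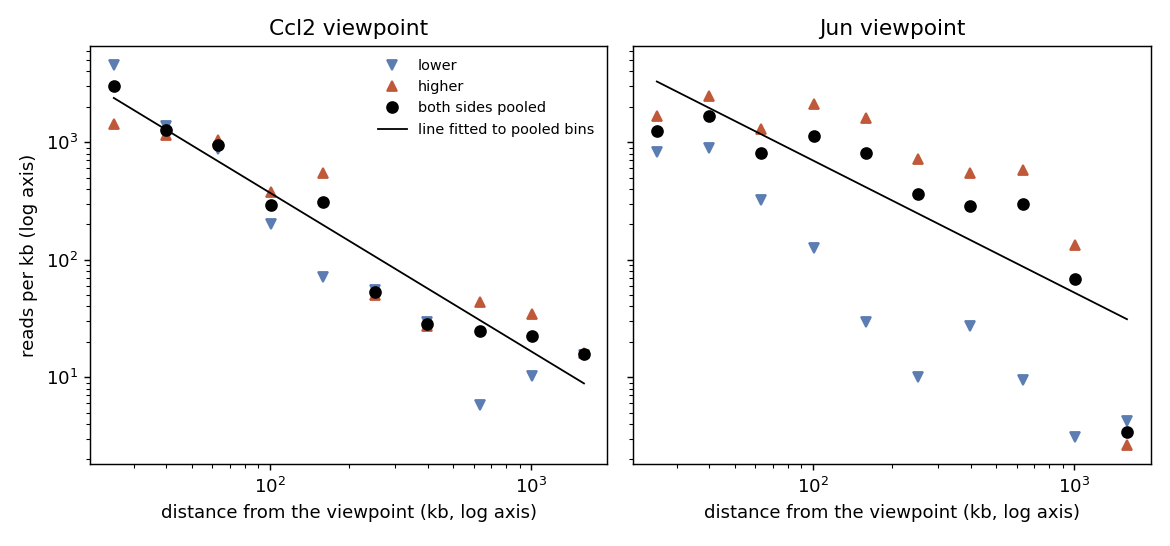
Reads per kb (vertical, log axis) in 10 bins of distance from 20 to 2000 kb (horizontal, log axis), for the lower side, the higher side and both pooled, 1 library per viewpoint; the line is the fit to the pooled bins, with slopes of -1.35 for Ccl2 and -1.12 for Jun. The 2 sides of Jun lie far apart from 100 to 1000 kb.

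The third question was whether contacts lay to one side of the promoter. As background, Ccl2 is transcribed towards higher and Jun towards lower coordinates. For Jun, 9.04% of the reads from 20 to 500 kb lay on the lower side (49929 of 552365 reads, block bootstrap interval 3.03 to 16.4%), so the higher side, which is upstream of Jun, held the rest. The lower-side share of Jun was 22.1% from 20 to 100 kb and 20.5% by ends with a read, both above that interval. For Ccl2, 48.8% lay on the lower, upstream side (130795 of 268219 reads, 16.1 to 75.0%). Blocks were redrawn within a side whatever their distance, so the width of this interval includes the fall of reads with distance. It cannot decide whether a side of Ccl2 was favoured. The sides of Ccl2 differed by distance. The lower side held 59.2% of the reads from 20 to 100 kb, and from 100 to 500 kb it held 21782 reads against 62139 on the higher side. From 500 to 1000 kb, 2.44% of Ccl2 ends on the lower side (1.82 to 3.20%) and 16.1% on the higher side (14.5 to 17.8%) had a read. For Jun the same class had 4.05% (3.22 to 5.03%) and 76.9% (74.9 to 78.8%).

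The fourth question was which regions exceeded the signal expected at their distance. For Ccl2, 10 regions reached 3 times the expectation, all on the higher side and 215 kb long in total. The one nearest to the promoter lay at 130 to 155 kb, at positions 81978193 to 82003192 of chromosome 11, just inside the drop in coverage. It held 30943 reads, 5.38 times the expectation (4.06 to 7.07), and 104 of its 118 ends had a read. Its ratio was 3.18 against a monotone expectation and 3.09 when ends with a read were counted instead of reads. The other 9 lay between 660 and 985 kb. The highest of them, at positions 82673193 to 82693192 (825 to 845 kb), reached 6.11-fold (3.55 to 9.24) with 28 of 76 ends covered. The regions at 82783193 to 82793192 (5.09-fold, 1.57 to 9.82) and 82823193 to 82833192 (5.02-fold, 1.13 to 10.2) rested on 6 and 7 ends with a read. The region at 82623193 to 82643192 reached 4.91-fold (2.69 to 7.64) and that at 82573193 to 82618192, with 57 covered ends, 4.01-fold (2.66 to 5.51). The remaining 4, at 82508193 to 82523192, 82648193 to 82663192, 82708193 to 82733192 and 82748193 to 82778192, reached 2.92- to 3.36-fold as merged regions. By presence of a read these 9 stood at 2.08 to 4.49 times the expectation and 6 of them below 3 times, among them those at 82783193 to 82793192 (2.12), 82823193 to 82833192 (2.57) and 82623193 to 82643192 (2.90). The expectation pools both sides, and the lower side of Ccl2 held 7.29 reads per kb from 500 to 1000 kb against 46.4 on the higher side, which enters these ratios. With a line fitted to each side, the 10 regions stood at 2.10 to 5.12 times the expectation and 5 of them below 3 times, among them that at 82573193 to 82618192 (2.97), and the intervals of those at 82783193 to 82793192 (3.65, 0.941 to 6.93) and 82823193 to 82833192 (3.58, 0.608 to 7.09) included 1. Called anew under that setting, 9 regions passed. When fragments were shuffled among positions of the same side and distance class, a test added after seeing the data, 39 of 100 shuffles gave 10 or more regions (median 9, highest 12). This shuffle keeps the level of each side within each distance class, so a raised stretch that fills much of a class is kept too. The number of regions did not exceed what the shuffle gave, but the shuffle cannot tell raised contact across such a class from scatter. The 3 longest gaps of Ccl2 lay at 81148194 to 81258193 on the lower side (0.08 of the expectation, 8 of 442 ends covered), at 82328193 to 82388192 on the higher side (0.17, 16 of 250 ends) and at 81028194 to 81083193 on the lower side (9 reads on 1 of 244 ends, where 1247 were expected); by presence of a read they stood at 0.188, 0.569 and 0.0559, with a line fitted to each side at 0.142, 0.134 and 0.0133, and against a monotone decay at 0.0915, 0.264 and 0.00619.

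For Jun, 8 regions passed, all on the higher side and 745 kb long in total, so that most of the stretch from 90 to 895 kb was called. The one with the highest ratio spanned 350 kb, at positions 95266073 to 95616072 of chromosome 4 (545 to 895 kb), held 206930 reads and reached 7.61-fold (7.08 to 8.14), with 84.3% of its 1366 ends covered. The region nearest to the promoter, at 94811073 to 94836072 (90 to 115 kb), held 72070 reads and reached 4.23-fold (3.37 to 5.18), and the one next to it, at 94841073 to 94921072, held 127369 reads and reached 3.78-fold (3.31 to 4.28). The other 5 lay at 94936073 to 94986072, 94991073 to 95076072, 95086073 to 95111072, 95116073 to 95176072 and 95186073 to 95256072 and reached 3.47- to 4.50-fold. By presence of a read the region at 90 to 115 kb stood at 1.72 and that at 120 to 200 kb at 2.18 times the expectation, and the other 6 at 3.07 to 5.02. The 3 longest gaps were all on the lower side, at 93721074 to 94101073 (0.04 of the expectation), 94301074 to 94671073 (0.14) and 94106074 to 94236073 (0.18); by presence of a read they stood at 0.130, 0.441 and 0.554. As for Ccl2, the expectation pools both sides, so the one-sided profile of Jun enters each of these ratios. With a line fitted to each side, the region from 545 to 895 kb fell to 4.83-fold and the other 7 to 2.16- to 2.82-fold, below the threshold as whole regions. Called anew with these lines, 19 regions passed, 12 on the higher side and 7 on the lower. The 3 gaps, in the order above, rose to 0.455, 0.893 and 1.83 times the expectation, and none stayed at 1/3 or less as a whole. Gaps called anew with these lines numbered 24, with 465 kb on the lower side and 90 kb on the higher. The 2 longest, at 93856074 to 93956073 (0.016 of the expectation) and 93981074 to 94036073 (0.060), lie inside the first of the 3 gaps. Against a monotone decay of both sides pooled, the gaps stood at 0.0133, 0.0957 and 0.0636 and the 8 regions at 1.62 to 2.76 times the expectation, and the region from 545 to 895 kb at 2.13 times, while 9 regions called anew under that setting passed.

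With a line fitted to each side only inside its drop in coverage, an expectation added after seeing the data, 1 region per viewpoint passed. Only the range inside the drops was searched, so the 9 Ccl2 regions beyond 660 kb were left out by construction. For Ccl2 it was 81983193 to 81998192 (135 to 150 kb), at 3.36-fold (2.46 to 4.35). For Jun it was 94821073 to 94831072 (100 to 110 kb), at 3.49-fold (2.68 to 4.31) with 43780 reads. Both lie within regions called against the pooled expectation. By presence of a read against the line of each side over 20 to 2000 kb, the Ccl2 region at 130 to 155 kb stood at 2.71 times the expectation (5.12 by reads) and the Jun region at 100 to 110 kb at 1.33 (4.01 by reads).

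**Figure D3:**
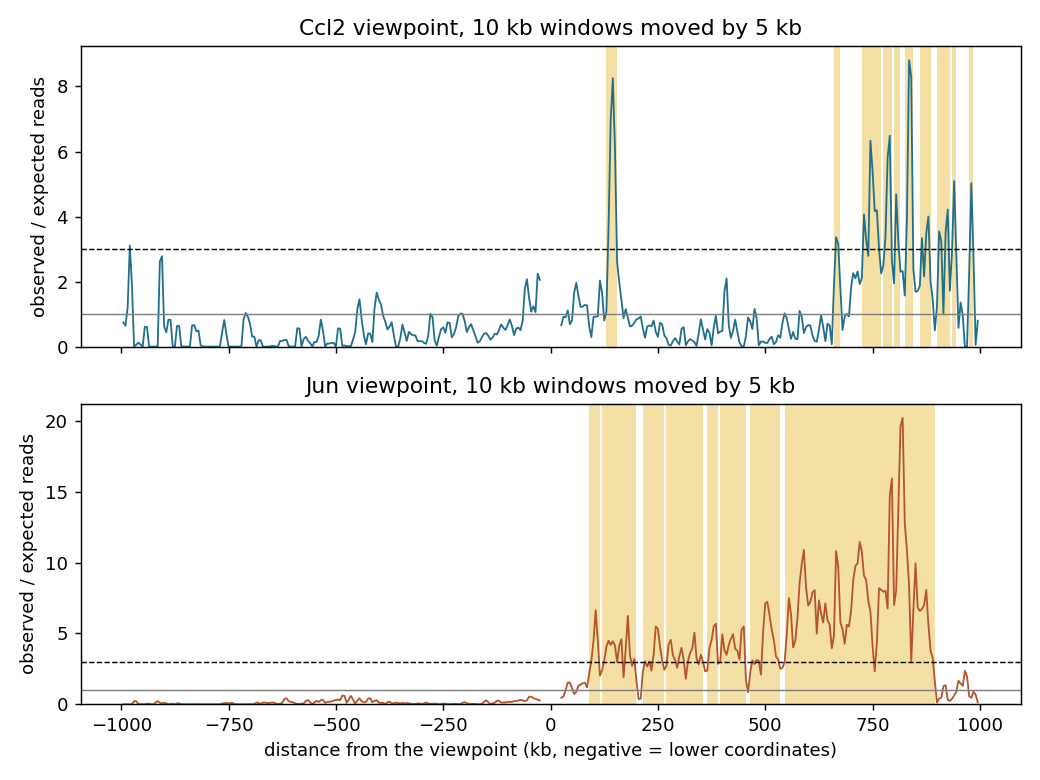
Ratio of observed to expected reads (vertical axis) in 10 kb windows against the distance from the viewpoint in kb (horizontal axis, negative for lower coordinates), with the expectation from the decay line of both sides pooled, 1 library each; the dashed line marks 3-fold and shading marks contact regions. The 10 regions of Ccl2 and the 8 of Jun all lie on the higher side.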

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

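The tests weighed here were chosen after the result was seen, except the shuffling of Ccl2 fragments across both sides; the shuffling within each side was added after that result, with its prediction written before its own. Fragment ends with several copies in the genome, left out of the main values and used only in 1 alternative, carried reads in both libraries: 85073 reads on 2405 of 61558 ends for Ccl2 and 100608 reads on 3128 of 99558 ends for Jun. These are 3.91% and 3.14% of such ends. Beyond 1 Mb, 3.66% of these ends had a read for Ccl2 (exact interval 3.52 to 3.82%) and 1.54% of unique ends (1.51 to 1.58%), and for Jun the shares were 2.84% (2.74 to 2.94%) and 1.19% (1.16 to 1.22%).

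The one-sided contact zone of Jun was weighed against 2 technical explanations. Unique ends per kb from 20 to 895 kb were 1.10 times as dense on the higher side, against a ratio of 13.8 in reads, which argues against a difference in the density of ends. The 10 ends with the most reads held 3.43% of the higher-side reads, which argues against a few strongly amplified ends. No biological explanation was tested, since both libraries come from 1 condition, and a rearrangement of this stretch in these cells was not examined.

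The 10 contact regions of Ccl2 were weighed against scatter between fragments. Shuffled among positions of the same distance class across both sides, fragments gave 10 or more regions in 0 of 100 shuffles (median 5, highest 9), but this shuffle also evens out the sides, so, as narrowed after that result, it argues only against scatter with both sides alike. Shuffled within the same side and distance class, they gave 10 or more in 39 of 100 (median 9, highest 12). This shuffle keeps the level of each side within each distance class, and with it a raised stretch that fills much of a class. Such levels together with scatter could account for the number of regions, raised contact across a class could too, and this stays open. Touching windows merge, so the number of regions cannot show whether signal within a side is grouped. Scaled to the number of unique ends in each region, their median fold was 4.23 against 4.46 unscaled, which argues against the density of ends. These tests concern the set of 10 and not any one region, and no biological explanation was tested.

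With a line fitted to each side over 20 to 2000 kb, Jun had 12 regions above expectation on the higher side, among them 570 to 750 kb at 4.70-fold and 760 to 885 kb at 6.05-fold. A candidate explanation is that a straight line across the drop at 895 kb is too steep inside it. Fitted inside the drop only, the slope on the higher side was -0.40 and 1 region was left there, and the 2 stretches stood at 1.03 (0.94 to 1.13) and 1.12 (0.97 to 1.27) of the expectation. Leaving the low coverage beyond the drop out of the fit makes the slope shallower by construction. The slope, the count of regions left and the ratios of the 2 stretches are no independent support, because the inner line was fitted to the same reads. They show only that the number of higher-side regions depends on whether the line crosses the drop. The region at 100 to 110 kb remained above 3-fold by reads. The 7 lower-side regions lie beyond the drop of that side, outside the range of the inner fit, and were not tested.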

How the results depend on the processing

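No paired analysis was possible because each viewpoint has 1 library, and no replicate could be left out. Values for Ccl2 come first in each pair. The share of reads within 100 kb (38.6% and 22.5%) was 31.6% and 20.7% with ends held to the 99th percentile, 8.32% and 6.72% by presence of a read, 32.9% and 19.4% with 10 kb left out around the viewpoint, 40.2% and 25.8% with 2 kb left out, 36.6% and 21.9% with ends of several copies, and 31.0% and 14.8% within 50 kb, 50.9% and 78.3% within 1000 kb; with second-cutter fragments only, that of Jun was 22.0%. Ccl2 was thus above Jun under each of these except within 1000 kb. The decay exponent was -0.83 and -0.66 by presence and -1.68 and -0.57 up to 500 kb, where the difference was 1.11. The share of the lower side for Ccl2, whose interval cannot decide between the sides, turned to 59.2% from 20 to 100 kb. That of Jun was 20.5% by presence and 22.1% from 20 to 100 kb. Contact regions of Ccl2 numbered 4 with 20 kb windows, 16 with 5 kb windows, 6 at 5-fold and 1 with the line fitted inside the drop, a range that leaves out 9 of them by construction, against 10; those of Jun numbered 25 with 5 kb windows, 4 at 2-fold, 19 with each side fitted separately (7 of them on the lower side, beyond its drop) and 1 with the line fitted inside the drop, against 8. Regions merge or split as windows and thresholds change, so these counts depend on both. With each side fitted separately, the gaps of Jun at 620 to 1000, 50 to 420 and 485 to 615 kb rose from 0.04, 0.14 and 0.18 to 0.455, 0.893 and 1.83 of the expectation. Gaps of Jun called anew under that setting numbered 24, against 8. Of 104 other settings of these results 73 stayed within their interval or within 1.5 times the count, and the drops in coverage did so under every setting tried; of 391 for the named regions and gaps 347 did, and 43 moved further without changing direction. These counts overstate stability. Leaving out 10 kb or 2 kb around the viewpoint could not change any value measured from 20 kb outwards, and wide intervals are hard to leave. The causes of the shifts above were not tested. Settings on ends with several copies, on second-cutter fragments, on the line inside the drop and on the drops were chosen after seeing the data. At this depth 1.38% and 1.09% of ends beyond 10 Mb had a read.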

Other observations

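Beyond some of the drops in coverage, contacts did not fall steadily with distance. The zones below were chosen after the profiles were seen. On the higher side of Ccl2, 22.2% of ends had a read from 660 to 900 kb, at positions 82508193 to 82748192 of chromosome 11 (exact interval 19.6 to 25.0%, 963 ends), above the 9.07% from 260 to 660 kb (7.74 to 10.6%) and the 7.31% from 1100 to 1500 kb (5.94 to 8.88%). In the 20 kb windows from 900 to 1100 kb, left out of these zones, the higher-side shares ran from 6.67 to 23.7%, so the rise had no clear end at 900 kb. On the lower side from 660 to 900 kb the share was 1.70% (1.00 to 2.71%). That side rose farther out, to 9.33 to 17.3% in the 20 kb windows from 1480 to 1600 kb. On the lower side of Jun, 17.4% of ends had a read from 320 to 560 kb, at positions 94161074 to 94401073 of chromosome 4 (14.7 to 20.3%, 736 ends), above the 8.28% from 160 to 320 kb (6.04 to 11.0%) and the 2.09% from 620 to 1000 kb (1.42 to 2.97%). From 1100 kb outwards the higher side of Jun showed no such rise. There 3.24% of ends had a read from 1100 to 1500 kb (2.27 to 4.48%), and no 20 kb window from 1100 to 2000 kb exceeded 6.45%. The stretch from its drop to 1100 kb was left out of this zone. Its shares fell unevenly, from 30.3% at 900 to 920 kb to 1.19% at 1080 to 1100 kb.

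Beyond 2 Mb from the viewpoint, covered ends were unevenly spread. Of 574 windows of 200.0 kb beyond 2 Mb from Ccl2, 33 had a larger share of ends with a read than the 3.89% that was the highest window in 100 shuffles of the far fragments. The highest were 67400001 to 67600000 (8.55%, 6.71 to 10.7%) and 32400001 to 32600000 (8.49%, 6.44 to 10.9%) on chromosome 11, against a median window of 1.08%. For Jun, 18 of 717 windows exceeded the 4.11% reached in shuffles, the highest being 100800001 to 101000000 (8.27%, 6.41 to 10.5%) and 98800001 to 99000000 (7.09%, 5.33 to 9.22%) on chromosome 4, against a median of 0.74%. These 2 lie at 6.18 and 4.18 Mb from the viewpoint, and the 2 of Ccl2 at -14.3 and -49.3 Mb. The shuffles ignored distance, and 1.75% of Jun ends had a read from 2 to 10 Mb against 1.09% beyond. Decay with distance is therefore not separated from clustering. The genes in these windows were not analysed here.

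Reads per covered end fell with distance, as did the share of covered ends. For Ccl2 the median was 548 reads per covered end from 5 to 20 kb, 114 from 20 to 100 kb and 45 beyond 10 Mb, and for Jun 336, 162 and 28. The shares of covered ends at these distances were 98.7%, 79.9% and 1.38% for Ccl2 and 94.5%, 88.7% and 1.09% for Jun. Reads also differed with the length of an end to its second-cutter site, a meaning of these lengths that rests on column names and values only. The later of the 2 length columns was taken for 3′ ends and the earlier for 5′ ends. Only unique ends of fragments with a second-cutter site were counted, and 55.4% of fragments for Ccl2 and 55.5% for Jun had no such site. From 5 to 300 kb away, ends of 0 to 100 bp held 542 reads on average for Ccl2 and 398 for Jun, ends of 100 to 400 bp 335 and 550, ends of 400 to 1000 bp 32.2 and 68.8, and the few longer ends 0 and 1.78. The shares with a read were 59.5% and 76.8%, 60.6% and 78.1%, 51.2% and 70.5%, and 0% and 66.7% in the same order.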
